A study of Mus musculus with 36 samples.

How the data were processed

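The 36 libraries were polyA RNA from CA1, CA3, LEC and MEC of wild-type mice, 3 libraries per region and condition (home cage, context, fear), from the Illumina TruSeq Stranded mRNA kit after TRIzol extraction, per the labels' protocols. Mice had been handled for 3 minutes a day over 5 days. The deposited values are whole-number read counts per gene. Reads were trimmed with Trimmomatic 0.33, aligned with STAR 2.7.10b to mm10 and counted with HTSeq 2.0.1, per the submitters' processing notes. The settings, the annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene, antisense genes and near-identical copies are uncertain.

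The table held 37315 genes and 0 lines without a gene, and the 36 files of single samples held the same counts as its columns. Gene identifiers were matched to the GENCODE M21 annotation of GRCm38, the assembly also called mm10: 35449 (95.0%) had a symbol, and the 1866 without one held 0.21% of counts. Library totals were 21871412 to 68974340 counts (median 28098008). Mean totals in home cage, context and fear were 34726979, 32897836 and 33223071 in CA1, 28024549, 25971348 and 30977483 in CA3, 24769422, 35369228 and 29871721 in LEC, and 41811850, 29267679 and 27986065 in MEC. Replicates of a group differed from each other by more than sampling noise in every group.

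Groups were taken from the tissue and treatment labels. For each region, the 9 libraries were filtered with filterByExpr, normalized with TMM and fitted with edgeR's robust quasi-likelihood model (6 residual degrees of freedom), and fear, context and home cage were compared with each other. Region contrasts, averaged over conditions, and region by condition interactions came from a fit of all 36 libraries (24 residual degrees of freedom; 17875 genes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with standard errors, CPM as mean and SD. Biological coefficients of variation were 0.209 in CA1, 0.234 in CA3, 0.216 in LEC and 0.143 in MEC. Cbln4 and Neo1 were also compared by exact two-sided permutation tests, in which 3 against 3 libraries cannot give a p under 0.1. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

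Fixed before the data were examined were the design, the alternatives and 27 gene lists: 9 of pathways (rapid and delayed activity-regulated, glucocorticoid-responsive, circadian clock, heat shock and chaperone genes, the cerebellin list, other synaptic adhesion molecules, glutamate receptors and GABA receptors), 2 of RNA quality (cytosolic ribosomal proteins and mitochondrially encoded genes) and 16 of cell types (dentate granule, CA1, CA2 and CA3 pyramidal cells, neocortical layers, subiculum, thalamus, striatum, interneurons, oligodendrocytes, astrocytes, microglia, endothelial cells, meninges and mural cells, choroid plexus and blood). Lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. Adjusted p of lists are over the 27 lists of a contrast. In the comparisons between conditions, no list passed with an estimated correlation.

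Named genes followed a rule fixed at the same time. Against home cage these were the 8 largest called rises and falls with a mean of at least 1 log2 CPM and no overlap between groups, and in each pathway list the 4 members of smallest p and every called member. For fear against context the 5 called genes of smallest p in each direction were to be named, for regions the 8 largest called differences in each direction with a mean of at least 4 log2 CPM and the cerebellin list, and for interactions the 8 genes of smallest p. Cbln4 and Neo1 were always named. The text prints a part of the genes that this rule selects. Chance gives no overlap between groups of 3 and 3 for 10% of genes.

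Alternatives were DESeq2's size factors within edgeR (RLE), no filter on low counts, the replicate number as a block, a marker covariate (dentate granule markers in CA1 and CA3, choroid plexus and meninges markers in LEC and MEC), DESeq2, a fit of all 36 libraries, and leaving out each library in turn (in the 36-library fit, the same replicate of a condition in all 4 regions). Added after seeing the data were offsets for GC content and transcript length (natural splines with 5 degrees of freedom per library), alone and with the block, a covariate for the oligodendrocyte markers in MEC, and leaving out context 2 and home cage 2 of CA1 and CA3. The correlation of deviations of same-numbered libraries over 10149 genes was above 0.1 for every pair in 2 of 12 comparisons between conditions within a region (CA1 fear and home cage at 0.30, 0.40 and 0.23, MEC context and home cage at 0.60, 0.33 and 0.76) and in 4 of 18 between regions.

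The procedure was tested on simulated data made from the real libraries' means and totals, with 200 changed genes in each fear against home cage comparison. Of 100 genes changed 2-fold, 65 were called in CA1, 45 in CA3, 43 in LEC and 78 in MEC, and of 100 changed 1.5-fold 14, 5, 5 and 52, with 7, 6, 3 and 7 false calls. Shared home cage libraries were simulated 20 times per region, with no gene changed. In both simulations genes were drawn independently, without differences between libraries that many genes share. The real libraries may therefore give more false calls. For 3 against 3 libraries all 10 splits were refitted, and for the 36-library results 100 splits. For correlations of responses between regions, the 10 splits by condition and replicate number were made alike in both regions.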

Results

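Messenger RNA was sequenced from 4 regions of the brain of wild-type C57BL/6 mice, the hippocampal fields CA1 and CA3 and the lateral (LEC) and medial (MEC) entorhinal cortex. The entorhinal cortex is the main cortical input to the hippocampus. In each region, 3 libraries came from mice left in the home cage, 3 from mice exposed to a context and 3 from mice given a foot shock, called fear here, which gave 12 groups of 3 and 36 libraries. Tissue was taken 90 minutes after the behaviour. Library totals ran from 21871412 to 68974340 counts with a median of 28098008, and 16163 genes were tested in CA1, 16145 in CA3, 16402 in LEC and 16314 in MEC. The labels do not tie a replicate number to a mouse, so libraries of different regions may share mice, and p-values measure the spread between these libraries.

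The first question concerned Cbln4 and Neo1, the genes named in the series title. Cbln4 (ENSMUSG00000067578, GRCm38 chromosome 2, 172036233 to 172043466) encodes a secreted synaptic organizer of the C1q family, and Neo1 (ENSMUSG00000032340, chromosome 9, 58874687 to 59036441) encodes neogenin, a transmembrane receptor. Cbln4 was most abundant in MEC, at 93.2 ± 15.5 CPM (counts scaled to library total; SD, n = 9 libraries), against 14.8 ± 5.86 in LEC, 12.1 ± 2.98 in CA3 and 4.05 ± 1.52 in CA1. MEC exceeded LEC by 2.7 ± 0.18 on the log2 scale (SE; adjusted p = 4.87e-12) and CA3 exceeded CA1 by 1.60 ± 0.18 (adjusted p = 5.95e-08). Neo1 was expressed in all 4 regions, at 119 ± 16.3 CPM in CA1, 123 ± 24.8 in CA3, 155 ± 19.9 in LEC and 142 ± 14.2 in MEC; the entorhinal regions exceeded the hippocampal fields by 0.30 ± 0.04 (adjusted p = 3.36e-07). After behaviour, Neo1 passed the test in CA3 after context exposure, where it rose from 90.7 ± 9.55 to 127 ± 9.58 CPM (SD, n = 3). The log2 change was 0.49 ± 0.13 (adjusted p = 0.045). The unadjusted edgeR p was 0.00252 there and 0.000574 in CA3 after fear, where the change was larger but did not pass. Between fear and context in CA3, Neo1 differed by 0.11 ± 0.13 (adjusted p = 0.628). The call therefore does not set context apart from fear for Neo1. Its other log2 values against home cage were 0.60 ± 0.13 in CA3 after fear (adjusted p = 0.15), 0.37 in CA1 after fear (0.102) and 0.31 after context (0.163), 0.35 in LEC after fear (0.573) and 0.17 after context (1), and 0.18 in MEC after fear (0.223) and 0.21 after context (0.313). Cbln4 passed in no comparison between conditions; its largest values were 0.88 ± 0.31 in LEC after fear (adjusted p = 0.573), 0.71 ± 0.39 in CA1 after context (0.311) and after fear (0.314), and 0.63 ± 0.21 in CA3 after context (0.0574), and in MEC it was 0.16 ± 0.16 after fear (0.525). Exact two-sided permutation tests of Neo1 gave 0.1, the smallest p that 3 against 3 libraries allow, for both comparisons with home cage in CA1, CA3 and LEC, and 0.2 for both in MEC. Those of Cbln4 gave 0.1 for both in CA3 and 0.2 to 0.7 in the other regions. The Neo1 call in CA3 was lost without CA3 context 2 or 3 (adjusted p = 0.146 and 0.165), without fear 1, 2 or 3 (0.078, 0.0573 and 0.0594) and without home cage 1 or 2 (0.099 and 0.173), and with GC and length offsets its log2 value was 0.26 (adjusted p = 0.105).

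**Figure D1:**
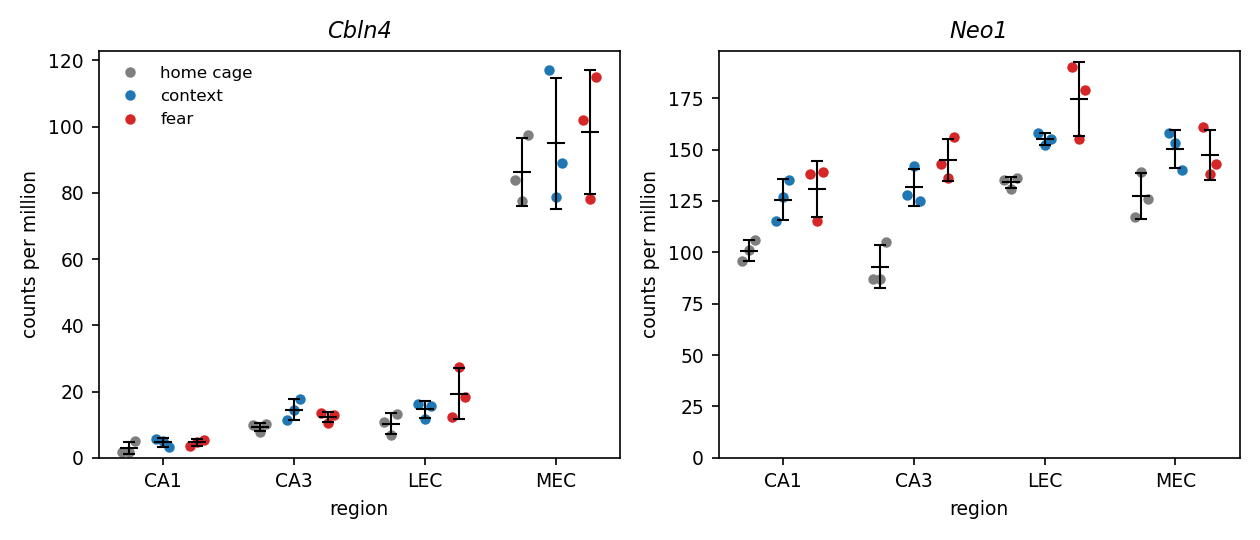
Cbln4 and Neo1 in CPM (y axis, normalized over the 36 libraries) by region and condition (x axis); points are libraries and bars the mean ± SD of 3. Cbln4 was 93.2 CPM on average in MEC and 4.05 CPM in CA1.

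Fear against home cage in MEC asked which genes differ after a shock in the region with the most Cbln4. Genes induced by neuronal activity rose together: 9 of 22 rapid and 15 of 32 delayed activity-regulated genes rose and none of these fell. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), a zinc finger transcription factor, rose from 102 ± 8.49 to 267 ± 45.6 CPM (log2 1.39 ± 0.12, adjusted p = 6.13e-05), with Fosb (1.75), Egr2 (2.18), Egr3 (1.60), Fos (1.15) and the synaptic effector Arc (1.43 ± 0.22). Among the delayed genes, Nptx2, which clusters AMPA receptors, rose by 1.83 ± 0.33, Ptgs2, the inducible cyclooxygenase, by 2.17 ± 0.45, the scaffold gene Homer1 by 1.02 ± 0.16 and the neurotrophin gene Bdnf by 0.97 ± 0.14. The largest rise among named genes was that of Scn4b (ENSMUSG00000046480, chromosome 9, 45138395 to 45154152), a sodium channel beta subunit, from 7.2 ± 0.686 to 45.3 ± 12 CPM (log2 2.65 ± 0.21, adjusted p = 6.13e-05), and that of Inhba was 2.58; the vesicle calcium sensor Syt2 (1.93 ± 0.16), the myosin-binding protein gene Mybpc1 (2.16), Cpne9 (2.30) and the potassium channel gene Kcng4 (1.88) followed. The largest falls were those of Dlk1 (-2.55 ± 0.55, adjusted p = 0.0155), the neuropeptide genes Nts (-2.33 ± 0.49) and Penk (-1.5 ± 0.33), the receptor genes Trhr (-1.62 ± 0.17) and Nmbr (-1.72), and Olfm4, Hc and Dsc2 (-2.12, -1.80 and -1.44). In all, 926 genes were higher and 633 lower at an adjusted p under 0.05, of which 218 differed at least 2-fold.

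Further lists moved in the same comparison. Of 22 glucocorticoid-responsive genes 9 rose, among them the kinase gene Sgk1 (1.26 ± 0.23, adjusted p = 0.00847), Hif3a (1.23), Cdkn1a (1.5), Zbtb16 (0.79) and Klf9 (0.69). Of 16 circadian clock genes 5 rose, including Bhlhe40 (1.16 ± 0.12), Per1 (0.68) and Hlf (0.55). Adjusted over the list alone, 9 rapid, 15 delayed, 12 glucocorticoid-responsive and 8 clock genes rose. The camera test, which compares a list with all other genes, gave adjusted p = 1.41e-05 for rapid, 1.19e-07 for delayed, 1.45e-06 for glucocorticoid-responsive and 4.83e-04 for clock genes; with an estimated correlation these were adjusted p = 0.18, 0.18, 0.312 and 0.18. The list of cerebellin and C1q-like ligands, receptors and neogenin partners did not pass as a list (median 0.155, adjusted p = 0.285), with Nrxn3 (0.57), Unc5b (0.85) and the netrin receptor gene Dcc (0.75) higher and C1ql2 lower (-1.28 ± 0.38; its groups overlapped, and with the oligodendrocyte covariate it was 0.35). Of other synaptic adhesion molecules, 3 rose, such as Cadm2 (0.67), and Cadm1 (-0.54) and Lrrtm2 (-0.60) fell (adjusted p = 0.042; adjusted p = 0.772 with an estimated correlation). Receptor genes went both ways, with Grin2a (0.88), Grm2 (0.88) and Gabbr2 (0.58) higher and Grik2 (-0.74) and Gabrg1 (-0.77) lower; the median of the GABA receptor list was -0.0184 and its mean 0.0434. Of the heat shock and chaperone list, Hspa1a rose (1.95) and Hspe1 fell (-0.47). Cytosolic ribosomal protein genes were lower (31 of 86 called, median -0.327, adjusted p = 2.23e-10; adjusted p = 0.772 with an estimated correlation).

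Markers of other cell types moved with these groups. Of 9 oligodendrocyte markers 6 rose in MEC after fear, with a median of 0.724 (adjusted p = 1.41e-05; adjusted p = 0.392 with an estimated correlation). Their mean level was 7.43 ± 0.24 log2 CPM after fear and 7.22 ± 0.12 after context against 6.67 ± 0.33 in home cage (SD, n = 3; exact p = 0.1 for each, the smallest possible). Endothelial markers (median 0.573) and interneuron markers (0.461) were also higher, with adjusted p of 0.00905 and 0.0141 and, with an estimated correlation, adjusted p of 0.312 and 0.321. With the oligodendrocyte marker level as a covariate, 78 genes were called in place of 1559, while the median change of the 1559 was 0.656 against 0.572 and their median SE 0.236 against 0.133. With a single fit of all 36 libraries 239 were called. Leaving out a MEC library gave 1025 genes without context 2, 958 without fear 1, 415 without fear 2, 306 without fear 3, 682 without home cage 1, 504 without home cage 2 and 4486 without home cage 3; of 72 named called genes, 30 lost the call without fear 2, 36 without fear 3, 29 without home cage 2 and 19 without home cage 1, while Egr1, Fosb, Arc, Bdnf, Homer1, Scn4b, Syt2, Sgk1 and Bhlhe40 passed without any single library.

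**Figure D2:**
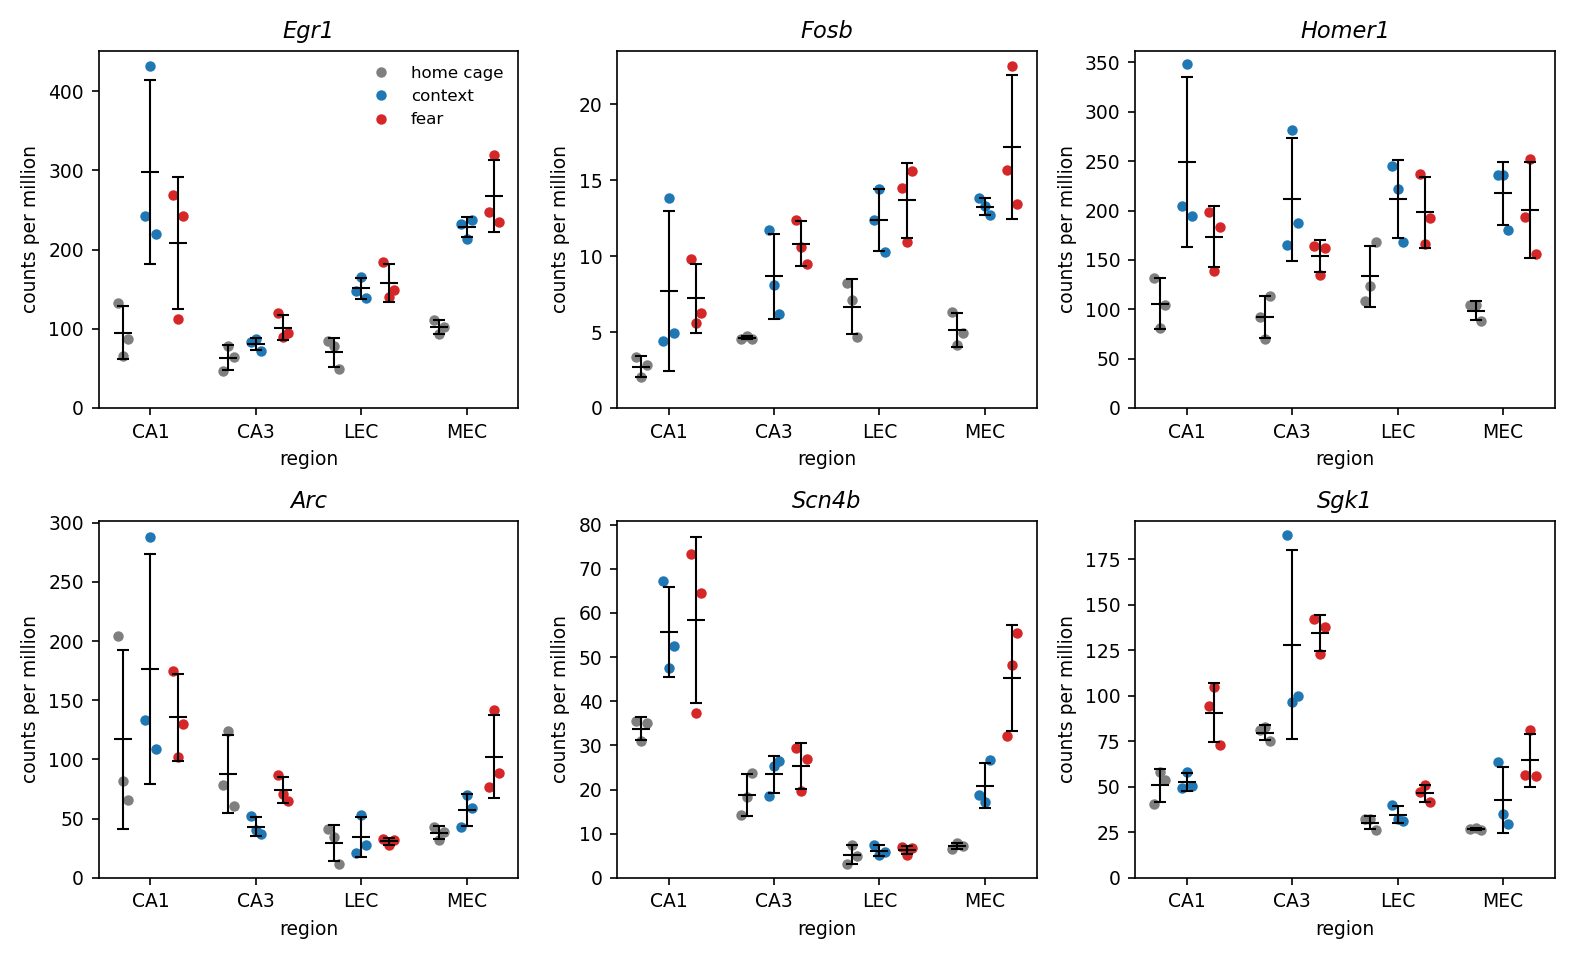
Egr1, Fosb, Homer1, Arc, Scn4b and Sgk1 in CPM (y axis, normalized within a region) by region and condition (x axis); points are libraries and bars the mean ± SD of 3. In MEC, Egr1 averaged 102 CPM in home cage, 228 after context and 267 after fear.

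Context against home cage in MEC asked what exposure without a shock does. Fewer genes passed, 81 higher and 12 lower, again with activity-regulated genes among them. Egr1 rose to 228 ± 12.4 CPM (log2 1.16 ± 0.12, adjusted p = 0.00134), Egr2 by 1.80 ± 0.34, Fosb by 1.37, Homer1 by 1.14 and the phosphatase gene Dusp4 by 0.99. Scn4b (1.54 ± 0.21, adjusted p = 0.00824), Syt2 (1.36), Mybpc1 (1.45) and the neurofilament gene Nefm (1.00) rose as after fear. Falls included the ribosomal protein genes Rpl38 (-0.76) and Rps28 (-0.71), the microglial adaptor gene Tyrobp (-0.71), Fxyd5 (-0.70), Hopx (-0.69) and Cst3 (-0.63), and the near-identical pseudogenes Pisd-ps1 and Pisd-ps2 (both -0.91), between which reads cannot be told apart with certainty.

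Over all genes, 4 rapid, 2 delayed, 1 glucocorticoid-responsive and 1 clock gene rose in MEC after context, and adjusted over the list alone 7, 14, 7 and 2 rose; 2 glucocorticoid-responsive genes fell over the list alone. The camera test gave adjusted p = 2.29e-09 for delayed and 0.00124 for rapid genes (adjusted p = 0.235 and 0.38 with an estimated correlation). Oligodendrocyte markers had a median of 0.531 (adjusted p = 2e-05; adjusted p = 0.38 with an estimated correlation), and ribosomal protein genes one of -0.46, with 2 of 86 called over all genes and 74 over the list alone (adjusted p = 4.76e-26; adjusted p = 0.38 with an estimated correlation). Same-numbered MEC context and home cage libraries deviated together; with the replicate number as a block 667 genes were called, and 576 with GC and length offsets as well, and 14 lists in place of 13 passed. With the oligodendrocyte covariate 51 genes were higher and 75 lower, and 16 of 23 named called genes lost the call; with a single fit of all 36 libraries 1 gene was called and 22 of the 23 lost the call. The median change of the 93 genes was 0.66 and 0.646 in these fits against 0.625, with a median SE of 0.155 and 0.201 against 0.113. Without MEC context 1, 2 or 3 the count was 12, 19 or 15, without fear 2 or 3 it was 47 or 31, without home cage 1, 2 or 3 it was 46, 32 or 356, and DESeq2 called 560. Egr1, Scn4b, Syt2 and Mybpc1 passed without any single library, whereas Fosb and Homer1 did not pass without context 1, and Egr2 did not without context 1, 2 or 3, fear 3 or home cage 1.

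Fear against context in MEC asked what a shock adds to exposure. No gene passed the edgeR test, with 2395 genes at an unadjusted p under 0.05. DESeq2 called 55, edgeR with the replicate block 784 and edgeR with no filter on low counts 35. Same-numbered MEC fear and context libraries did not all deviate together (0.36, -0.0077 and 0.28), so the data give the block no clear basis here. Scn4b averaged 45.3 ± 12 CPM after fear and 20.9 ± 5.19 after context. Glucocorticoid-responsive genes (median 0.311, adjusted p = 1.08e-05) and rapid activity-regulated genes (0.265, adjusted p = 0.0104) were higher after fear as lists, with adjusted p = 0.44 for each with an estimated correlation. Endothelial markers (median 0.445, adjusted p = 0.00435) were higher as well and GABA receptors lower (-0.152, adjusted p = 0.0433), with adjusted p = 0.44 and 0.798 with an estimated correlation. edgeR called 33 genes without MEC fear 1 and 32 without home cage 3.

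In the fits of 9 libraries, context against home cage in CA3 gave the most called genes of any condition comparison. Of these, 931 were higher and 1312 lower, and 735 differed at least 2-fold. The smallest adjusted p was 0.045, so all these calls lay just under the threshold of 0.05. With the replicate block or with GC and length offsets this comparison gave 1330 and 413, fewer than fear against home cage in MEC (3783 and 1911). Same-numbered libraries did not all deviate together in either comparison, so the data give the block no clear basis there. Homer1 rose from 91.9 ± 21.5 to 211 ± 62.2 CPM (log2 1.20 ± 0.22, adjusted p = 0.045), with Tent5a (1.29), the copper transporter gene Atp7a (1.18), the transcription factor gene Fosl2 (1.15), Tll1 (1.10), Zdbf2 and Palm2 (1.09 each) and the oxytocin receptor gene Oxtr (1.06). Falls included those of Rpl36 (-3.61 ± 0.92, adjusted p = 0.0459) and Rplp1 (-2.99), which encode ribosomal proteins, Plk5 (-3.61), a marker of dentate granule cells, the respiratory chain gene Uqcrq (-2.47), Metrn (-2.45), Ssbp4 (-2.45) and Rex1bd (-2.40). Much of the home cage mean of several of these came from home cage 2: the 3 home cage libraries averaged 30.3 ± 32.4 CPM for Rpl36, 225 ± 195 for Rplp1 and 38.9 ± 34.9 for Uqcrq. Without that library the log2 values were -2.25 for Rpl36, -2.01 for Rplp1, -1.42 for Uqcrq, -1.52 for Metrn, -1.31 for Ssbp4, -1.45 for Rex1bd, -1.79 for Hba-a1 and -3.04 for Plk5 (adjusted p = 0.173 to 0.175). The alpha globin gene Hba-a1 fell by 2.52 on the log2 scale, and its near-identical copy makes its counts uncertain. Rapid activity-regulated genes went both ways: 3 rose and Arc fell (-1.02 ± 0.24), and the list had a median of -0.35 (adjusted p = 0.766). Of the delayed genes 8 of 32 rose, such as Nr4a2 (0.96), with 10 rising and 2 falling adjusted over the list alone.

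Synaptic and chaperone genes were among those that rose in CA3 after context. Of 37 adhesion molecules 9 rose, such as Nlgn3 (0.68), and Ntng2 (-1.41) and Lrfn1 (-1.52) fell. In the cerebellin list, the genes that rose included Neo1, Unc5d (0.99) and Nrxn3 (0.73); the list median was 0.335, its mean -0.0111 and its test was not passed (adjusted p = 0.347). GABA receptor genes had a median of 0.524 (adjusted p = 0.00228), with Gabrg3 at 0.98, and chaperone genes one of 0.44 (adjusted p = 0.00702), with Hspa5, the main chaperone of the endoplasmic reticulum, at 0.85. Of the glutamate receptors, Grm5 (0.68) and Gria4 (0.54) rose and Grin2c (-1.10), Grin2d (-1.16) and Grik5 (-1.04) fell, with a list median of 0.338 and mean of -0.0354; of the glucocorticoid-responsive genes, Errfi1 rose (0.91) and Mt2 fell (-1.91). Ribosomal protein genes fell in 49 of 86 cases (median -0.81, adjusted p = 2.17e-15), as did 4 of 5 blood genes (median -1.52) and 4 of 9 microglial markers (median -0.85). Blood genes averaged 0.909 ± 0.433 log2 CPM after context and 2.39 ± 0.425 in home cage (SD, n = 3; exact p = 0.1). With an estimated correlation these lists each had adjusted p = 0.815. In place of 2243 genes, 0 were called without any one of CA3 context 2 or 3, fear 1, 2 or 3, or home cage 1 or 2, with 5429 without context 1 and 3369 without home cage 3. The count was also 0 without both context 2 and home cage 2, and 0 with a marker covariate, against 4128 with DESeq2.

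On the first principal component of CA3, context 2 lay at -69.2 and home cage 2 at 77, against -47.1 to 23 for the other 7 libraries. In CA1, context 2 lay at 61.2 and home cage 2 at -55.2, against -36.6 to 17.8 for the others. Each lay on the side of the rest of its group in both regions. CA1 context 2 had Egr1 at 432 and Homer1 at 348 CPM (220 to 243 and 194 to 205 in the other context libraries), and CA1 home cage 2 had 66 and 80.7, the lowest of its group. In CA3, Homer1 was at 282 in context 2 and 70.1 in home cage 2, the highest and lowest of their groups. Egr1 hardly differed between these libraries (87.5 and 78.8). Arc, lower in CA3 after context, was at 40.5 in context 2, against 52.0 and 36.9 in the other context libraries. It was at 124 in home cage 2, against 78.2 and 60.3 in the other home cage libraries. The rapid list was at 2.27 log2 CPM in CA3 context 2, against 2.51 and 1.92 in the other context libraries. In home cage 2 it was at 3.03, against 2.31 and 2.16 in the other home cage libraries. With labels exchanged within a pair, each library would lie on the far side of the opposite group. In CA1 the component and the activity-regulated genes argue against an exchange. In CA3 the component, Homer1 and Arc run with the labels. The rapid list, which holds Arc, does not decide. CA3 home cage 2 lay above every other home cage and context library of CA3, and context 2 lay within the range of both groups. An exchange in CA3 stays open.

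Fear against home cage in CA3 gave 1 called gene, the unnamed model Gm13340, which was lower and was named here after its value was seen. At an unadjusted p under 0.05 there were 3047 genes, and DESeq2 called 659. Delayed activity-regulated genes were higher as a list (median 0.381, adjusted p = 1.86e-04), with 4 rising adjusted over the list alone, and so were adhesion molecules (0.342, adjusted p = 1.99e-06), with 6; both had adjusted p = 0.329 with an estimated correlation. The cerebellin list had a median of 0.369 (adjusted p = 0.00288; adjusted p = 0.329 with an estimated correlation), and the rapid list a median of -0.114 with a mean of 0.157 (adjusted p = 0.17). Ribosomal protein genes had a median of -0.575 (adjusted p = 2e-17; adjusted p = 0.379 with an estimated correlation) and blood genes one of -1.12 (adjusted p = 0.00288; adjusted p = 0.329 with an estimated correlation). edgeR called 2 genes without CA3 context 1 and 462 without home cage 3, and 0 without context 3, fear 1, 2 or 3, or home cage 1 or 2. Fear against context in CA3 gave no called gene with edgeR, 3785 at an unadjusted p under 0.05, 778 with DESeq2 and 3383 with edgeR without CA3 context 1. In that comparison CA1 pyramidal markers had a median of 0.976 (adjusted p = 0.00937; adjusted p = 0.725 with an estimated correlation).

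In CA1, edgeR with the 9 libraries and the filter on low counts called no gene after fear or after context. With no filter it called 558 and 197, and in a single fit of all 36 libraries 752 and 905. At an unadjusted p under 0.05 there were 3553 and 3449 genes, and the smallest adjusted p were 0.0623 and 0.104; DESeq2 called 1458 and 1068. Members of the preset lists did not pass either. After fear, Sgk1 averaged 90.6 ± 16.3 CPM against 50.9 ± 8.99 in home cage (log2 0.84 ± 0.16, adjusted p = 0.0623), Bhlhe40 had 0.82, Nrxn3 0.86 and Nptx2 0.96 (adjusted p = 0.0623, 0.0623 and 0.067). After context, Egr1 averaged 299 ± 116 against 95 ± 33.6 CPM (1.65 ± 0.39, adjusted p = 0.105), Homer1 had 1.23 ± 0.25 and Bhlhe40 1.07 ± 0.17 (adjusted p = 0.104 for both). Adjusted over the list alone, 6 glucocorticoid-responsive genes and 2 delayed genes rose after fear, and 3 rapid genes, 10 delayed genes and 7 GABA receptors rose after context, with 1 delayed gene and 1 GABA receptor falling.

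As lists, glucocorticoid-responsive genes in CA1 had a median of 0.446 after fear (adjusted p = 0.00277), adhesion molecules 0.348 (2.72e-05), glutamate receptors 0.407 (0.00277) and the cerebellin list 0.368 (0.00259), with adjusted p = 0.554, 0.587, 0.554 and 0.554 with an estimated correlation. Ribosomal protein genes had medians of -0.715 after fear (adjusted p = 2.19e-32) and -0.643 after context (6.31e-25), with adjusted p = 0.554 and 0.568 with an estimated correlation. Dentate granule markers had a median of -1.33 in CA1 after context (adjusted p = 0.0151) and CA1 pyramidal markers one of 0.934 (0.00258), both with adjusted p = 0.568 with an estimated correlation. The 3 context libraries held dentate markers at 3.63, 2.12 and 5.44 log2 CPM, and CA1 home cage 2 had 12.15% of its counts in mitochondrially encoded genes. Same-numbered CA1 fear and home cage libraries deviated together, and the replicate block called 715 genes, or 0 with GC and length offsets as well. Without CA1 home cage 1 or 3, edgeR called 1108 or 527 genes after fear and 350 or 4 after context. Between fear and context in CA1 no gene passed with edgeR (918 at an unadjusted p under 0.05, 15 with DESeq2, 3 without context 3), and dentate granule markers had a median of 1.22 (adjusted p = 4.7e-05; adjusted p = 0.596 with an estimated correlation).

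In LEC, edgeR with the 9 libraries and the filter on low counts called no gene in any comparison. With no filter it called 4 after fear and 1 after context, and with GC and length offsets 1 after each. At an unadjusted p under 0.05 there were 1242 genes for fear against home cage, 403 for context against home cage and 207 for fear against context, and DESeq2 called 40, 3 and 0. Egr1 averaged 70.3 ± 18.6 CPM in home cage, 151 ± 14.0 after context and 158 ± 23.8 after fear (log2 1.17 ± 0.19 after fear, adjusted p = 0.382). Fosb had 1.03, Hif3a 1.15 and Sgk1 0.62 after fear, and Dusp4 1.01 after context, none past the test. Delayed activity-regulated genes had list medians of 0.237 after fear (adjusted p = 0.00541) and 0.2 after context (4.92e-07), and glucocorticoid-responsive genes 0.28 after fear (0.00422), with adjusted p = 0.487, 0.622 and 0.487 with an estimated correlation. Adjusted over the list alone, 3 rapid and 4 glucocorticoid-responsive genes rose after fear, and 3 rapid and 1 delayed gene after context. LEC home cage 3 stood apart, at 56.8 on the first principal component against -42.9 and -35.7 in the other home cage libraries. It had the lowest level of the rapid list (1.85 log2 CPM against 2.87 and 2.66) and of the glucocorticoid-responsive list (3.93 against 4.35 and 4.24), so part of these rises may come from it. Ribosomal protein genes had medians of -0.482 after fear (adjusted p = 1.68e-29; adjusted p = 0.487 with an estimated correlation) and -0.282 after context (adjusted p = 2.06e-15; adjusted p = 0.829 with an estimated correlation). Without LEC home cage 3, 56 genes were called for fear against home cage.

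**Figure D3:**
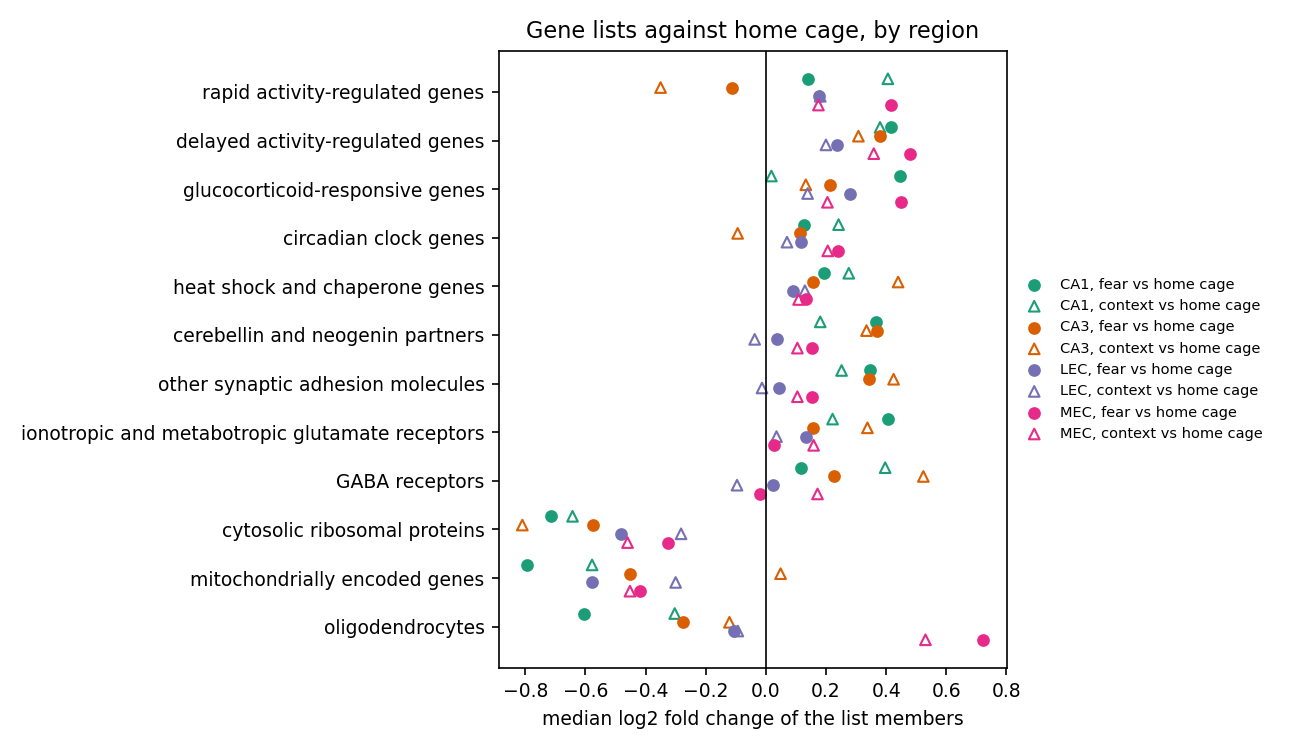
Median log2 fold change (x axis) of the 9 pathway lists and of ribosomal, mitochondrial and oligodendrocyte genes (y axis) by region; filled circles are fear and open triangles context, each against home cage. The ribosomal list lay between -0.81 (CA3 after context) and -0.282 (LEC after context).

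**Figure D4:**
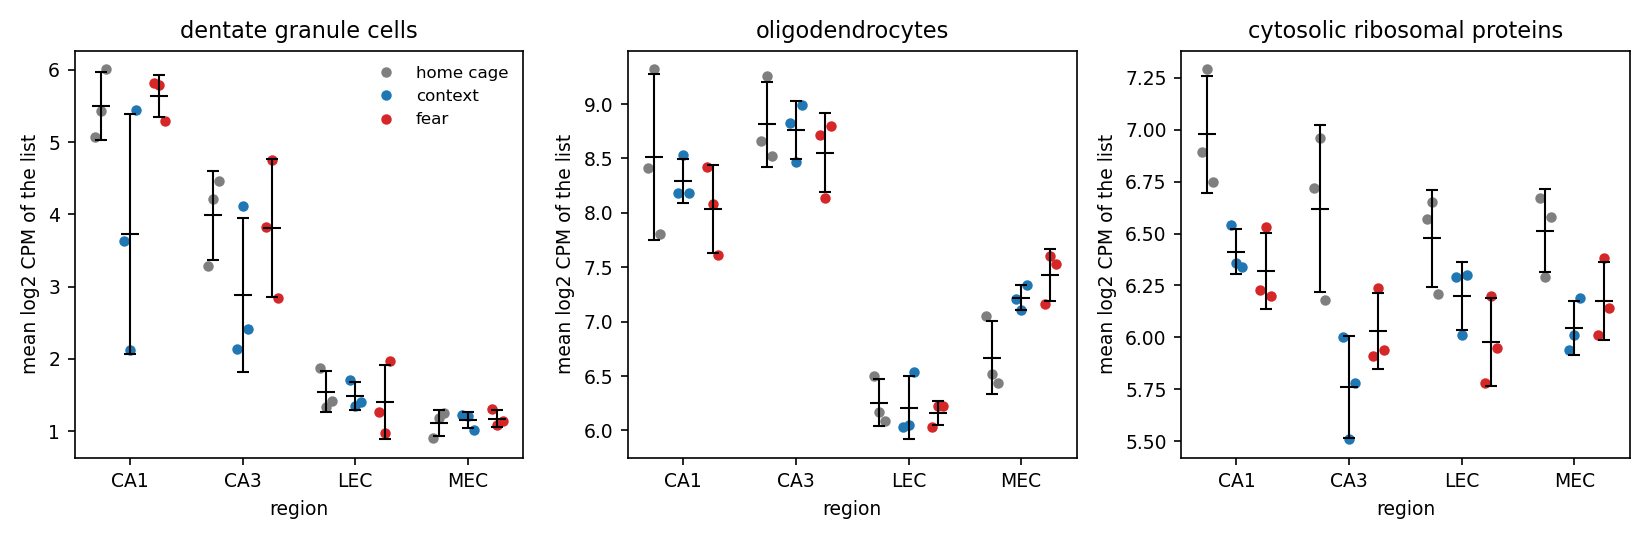
Mean log2 CPM (y axis) of dentate granule, oligodendrocyte and ribosomal protein genes in each library, by region and condition (x axis). CA1 context libraries held dentate markers at 3.63, 2.12 and 5.44, and MEC oligodendrocyte markers averaged 6.67 in home cage and 7.43 after fear.

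The region comparisons asked how the 4 regions differ, with the 3 conditions averaged. Between MEC and LEC, 1573 genes were higher and 1536 lower in MEC, 690 of them at least 2-fold. Syt2 (2.82 ± 0.26), Tshz2 (2.74), Nrep (2.50), Satb1 (1.89), Grm2 (1.87), Nr4a2 (1.70) and Scn4b (1.66) were higher in MEC, and Npy2r (-2.62 ± 0.23), Car12 (-2.46), Penk (-2.35), Ndst4 (-2.20), Ptgs2 (-2.00) and Htr2c (-1.91) were lower. In home cage libraries, normalized within a region, Scn4b overlapped between MEC (6.49 to 7.86 CPM) and LEC (3.24 to 7.47). Besides Cbln4, its family member Cbln1 was higher in MEC (2.20 ± 0.19), whereas C1ql3 (-0.95), Unc5d (-0.996) and Nrxn3 (-0.46) were lower. All 9 oligodendrocyte markers were higher in MEC (median 0.817, adjusted p = 1.51e-07; adjusted p = 0.235 with an estimated correlation). Home cage libraries alone gave 185 genes.

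Between CA3 and CA1, 2940 genes were higher and 2609 lower in CA3, 1278 of them at least 2-fold. Socs2 (3.12 ± 0.21), the guidance cue gene Slit2 (2.85), Cpne4 (2.58), Spock1 (2.53) and the kainate receptor gene Grik4 (2.53) were higher in CA3, and Tshz2 (-3.00 ± 0.50), Wfs1 (-2.92), Ndst4 (-2.56), Adgrl2 (-2.51) and Ccn3 (-2.33) were lower. Of 7 CA3 pyramidal markers, Socs2 and Grik4 included, 6 were higher in CA3 (median 2.16, adjusted p = 0.0127 with an estimated correlation), and all 6 CA1 pyramidal markers, among them Wfs1 and Ccn3, were lower (median -1.92; adjusted p = 0.0551 with an estimated correlation). Clock genes were lower in CA3 in 14 of 16 cases (median -0.564, adjusted p = 0.00283 with an estimated correlation). The netrin receptor genes Unc5d (1.56), Unc5c (1.45) and Dcc (1.16) were higher in CA3. All 7 dentate granule markers were lower in CA3 (median -1.35; adjusted p = 0.256 with an estimated correlation). Home cage libraries alone gave 639 genes.

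Between the entorhinal and the hippocampal regions, 4558 genes were higher and 4534 lower in entorhinal cortex, 2345 of them at least 2-fold. The calcium pump gene Atp2b4 (4.40 ± 0.13), Dcn (4.21), the kinase gene Camk2d (4.07) and Cobl (3.93) were higher, and the calcium sensor gene Hpca (-3.47 ± 0.08), Shisa6 (-3.42), Pkp2 (-3.39) and the transcription factor gene Zbtb20 (-2.92) were lower. Of 12 neocortical layer markers 11 were higher (median 1.55, adjusted p = 4.08e-05 with an estimated correlation), and of 22 members of the cerebellin list 11 were higher and 5 lower. All 9 oligodendrocyte markers were lower (median -1.83; adjusted p = 0.207 with an estimated correlation), and 8 of 10 markers of meninges and mural cells, Dcn included, were higher (median 1.46; adjusted p = 0.224 with an estimated correlation). Home cage libraries alone gave 4794 genes.

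Whether the fear response differs between regions was tested as an interaction in all 36 libraries. Between MEC and LEC, 3 genes passed, each with the larger response in MEC: Scn4b (difference 2.36 on the log2 scale, adjusted p = 0.00571), the neurofilament gene Nefh (1.37, adjusted p = 0.00571) and the vesicle fusion gene Vamp1 (1.16, adjusted p = 0.00128). The differences for Cbln4 (-0.72, adjusted p = 0.808) and Neo1 (-0.17, adjusted p = 0.837) did not pass. Delayed activity-regulated genes differed as a list (median 0.266, adjusted p = 7.69e-04; adjusted p = 0.478 with an estimated correlation), as did glucocorticoid-responsive genes (0.286, adjusted p = 0.0155; adjusted p = 0.799 with an estimated correlation). Cell type lists moved with these: oligodendrocyte markers (0.835, adjusted p = 3.1e-06), interneuron markers (0.428, adjusted p = 8.89e-04), choroid plexus markers (-1.97, adjusted p = 0.0261) and ribosomal protein genes (0.0813, adjusted p = 0.0261) differed, with adjusted p = 0.478, 0.136, 0.873 and 0.907 with an estimated correlation. DESeq2 called 18 genes, and edgeR called 1 without home cage 2 or without fear 3 of all 4 regions, 6 without fear 1 and 267 without home cage 3. No gene passed with edgeR between CA1 and CA3 (712 at an unadjusted p under 0.05, 2 with DESeq2), between entorhinal and hippocampal regions (2072, 48 with DESeq2) or for any interaction (1822, 115 with DESeq2).

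Across genes, which are not independent replicates, the log2 changes after fear correlated between regions with Pearson's r of 0.45 for CA1 and CA3 (0.34 to 0.48 leaving out 1 library), 0.40 for CA1 and MEC (0.30 to 0.40), 0.24 for CA3 and MEC (0.16 to 0.31), 0.21 for CA3 and LEC (0.081 to 0.31), 0.18 for CA1 and LEC (0.042 to 0.29) and 0.18 for LEC and MEC (0.0068 to 0.28). Spearman's rho was 0.56, 0.50, 0.31, 0.25, 0.26 and 0.23 in that order. After context, r was 0.31 for CA3 and MEC (0.069 to 0.40 leaving out 1 library), 0.30 for CA1 and MEC (0.20 to 0.30), 0.25 for CA1 and CA3 (0.12 to 0.28), 0.23 for LEC and MEC (0.12 to 0.23), 0.11 for CA1 and LEC (0.028 to 0.15) and 0.11 for CA3 and LEC (-0.062 to 0.29). In CA3 and MEC after context, 26 genes were called higher in both (4.83 expected of independent lists) and 8 lower in both (1 expected), although the CA3 calls were 0 without any one of 7 libraries. Same-numbered fear libraries of CA1, CA3 and LEC deviated together (0.15 to 0.54), as did context libraries of LEC and MEC (0.24 to 0.67), so these may share mice. Same-numbered libraries of different conditions did so too, in CA1 (fear and home cage) and MEC (context and home cage). The correlations therefore do not settle whether mice are shared. In a test chosen after these values were seen, the 6 libraries were split the same way in both regions. After fear, the real split had the highest r of 10 for CA1 and CA3 (highest other 0.37), CA1 and MEC (0.25), CA3 and MEC (0.14) and LEC and MEC (0.16), whereas 5 of 10 splits were as large for CA1 and LEC and 4 for CA3 and LEC. After context it was highest for CA1 and MEC (0.09) and LEC and MEC (0.15), and 2 of 10 were as large for CA1 and CA3 and for CA3 and MEC, and 4 of 10 for LEC with CA1 and with CA3. With 10 splits no share can be under 0.05.

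Fear and context responses share their home cage libraries, which alone gave a simulated r of 0.50 in CA1 and CA3, 0.51 in LEC and 0.49 in MEC; the observed r were 0.66, 0.60, 0.75 and 0.64. The covariances were 0.15, 0.20, 0.13 and 0.10 in CA1, CA3, LEC and MEC against simulated values of 0.062, 0.066, 0.065 and 0.034. In MEC, 79 genes were higher and 9 lower in both comparisons, against 4.6 and 0.466 expected of independent lists and 0.05 and 0 in simulation. The simulation changed no gene, so hardly any gene could be called in both, and lists with shared controls are not independent. Neither value therefore measures how much of this overlap the shared libraries give. Splitting 3 home cage libraries would leave fewer than 2 in a part, so part of the excess may come from the shared libraries.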

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

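Of the tests in this part, both of the dissection axis were chosen after the result was seen, the bound for the activity-regulated genes after its value was known, and the offsets and the oligodendrocyte covariate are alternatives added after seeing the data. The number of splits of the 36-library results was raised to 100 after a smaller draw had been seen. In 3 genes the fear response differed between MEC and LEC by a test of the interaction: Vamp1 by 1.161, Nefh by 1.366 and Scn4b by 2.359 on the log2 scale, with adjusted p of 0.00128, 0.00571 and 0.00571. Of 100 splits, the real split alone gave as many as 3 genes, and the highest of the others gave 1. These splits shuffled the conditions within each region, so they also removed condition effects common to both regions. They therefore do not test a difference between MEC and LEC alone.

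The MEC fear response, 1559 genes, can be set against 3 technical explanations. Over the 1549 called genes measured, the fear change followed the MEC minus LEC difference of the context libraries (Pearson's r = 0.55 and Spearman's rho = 0.57 across genes; r = 0.27 over all genes). A difference in dissection along the axis from MEC to LEC may therefore account for part of the fear change. The response of the MEC context libraries themselves may add to this r, by an amount that was not measured. The dissection axis accounts less well for the 24 called activity-regulated genes, 13 of which were higher and 11 lower in MEC than in LEC (median 0.028, interquartile range 0.59, against 0.968 after fear). With the oligodendrocyte covariate the median change was largely kept, at 0.656 against 0.572 without it, and at 0.884 against 0.968 for the activity-regulated genes. The calls themselves were not kept: 61 of 1559 and 1 of 24 were still called, with a median SE of 0.236 in place of 0.133. The marker level itself did not overlap between fear (7.16 to 7.6 log2 CPM) and home cage (6.44 to 7.05). The covariate therefore overlaps with the comparison, and this fit does not decide whether white matter is the whole cause. GC content and length as the whole cause are argued against by the offsets (median 0.421, SE 0.0996, 1081 genes still called). A response to the behaviour and uneven dissection both stay open. Fear against home cage does not separate the shock from the exposure, and fear against context called 0 genes in MEC.

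Splits of the libraries tell little within a region, where 3 against 3 libraries give 10 splits, too few for a share under 0.05. In MEC the real counts were 1559 after fear (highest other split 0), 93 after context (1) and 0 between them (0), each with 1, 1 and 10 of 10 splits as large. In CA3 they were 2243 after context (0), 1 after fear (0) and 0 between them (0), with 1, 1 and 10 splits as large. In CA1 and LEC all 6 real counts were 0, so that all 10 splits were as large. The highest other split was 83 for CA1 fear against home cage (fear 1, fear 3 and home cage 1 against the rest) and 875 for LEC fear against home cage (fear 1, fear 2 and home cage 3 against the rest), and 0 for the others, and both of these point to a structure of the samples apart from their groups. Among 100 splits of the 36 libraries, the real split alone was as large for MEC against LEC (3109, highest other 497), CA3 against CA1 (5549, highest other 3499) and entorhinal against hippocampal regions (9092, highest other 414). A share of 1 in 100 is the smallest that 100 splits can give, so it argues against chance for these without excluding it. A split can keep many of the real region labels, so the CA3 against CA1 split with 3499 genes may hold part of the region difference. Which labels it kept was not recorded. For interactions of CA1 and CA3, of entorhinal and hippocampal regions and of any kind, the real counts were 0. All 100 splits were as large in each, and the highest others were 1091, 1 and 13. What the split with 1091 genes reflects was not tested.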

How the results depend on the processing

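The offsets, the oligodendrocyte covariate and the fits without both CA1 or CA3 libraries in doubt were added after the data had been seen. Of 297 values of named genes, 294 kept their direction and their side of the threshold with RLE, 268 with the replicate block and 256 with no filter. The marker covariate kept 146 of 213, GC and length offsets 147 and the fit of all 36 libraries 118, and the oligodendrocyte covariate kept 16 of 99 in MEC. For counts of genes the cause of a change was not tested. Leaving out libraries leaves fewer samples, yet some counts rose, as from 1559 to 4486 in MEC after fear without home cage 3.

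In CA1, fear against home cage gave 0 genes, and 558 with no filter, 715 with the block (0 with block and offsets), 1458 with DESeq2, 752 in the fit of all 36 libraries and 0 to 1108 leaving out a library. Context against home cage gave 0, and 197 with no filter, 1068 with DESeq2, 905 with all 36 and 0 to 350 leaving out a library; fear against context gave 0, and 15, 1 and 0 to 3 with the last 3 of these. In CA3, fear against home cage gave 1, and 15 with no filter, 0 with the block, 0 with the marker covariate, 62 with offsets, 2 without context 2 and home cage 2, 659 with DESeq2, 1235 with all 36 and 0 to 462 leaving out a library. Context against home cage gave 2243, and 1330 with the block, 0 with the marker covariate, 413 with offsets, 0 without context 2 and home cage 2, 4128 with DESeq2, 5065 with all 36 and 0 to 5429 leaving out a library. Fear against context gave 0, and 2, 778, 1 and 0 to 3383 with the last 4 of these.

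In LEC, fear against home cage gave 0, and 4 with no filter, 1 with offsets, 40 with DESeq2 and 0 to 56 leaving out a library; context gave 0, and 1 with no filter, 1 with offsets, 3 with DESeq2 and 0 to 0 leaving out a library, and fear against context 0 throughout. In MEC, fear against home cage gave 1559, and 3783 with the block, 78 with the oligodendrocyte covariate (29 higher, 49 lower), 2447 with DESeq2, 239 with all 36 and 306 to 4486 leaving out a library. Context gave 93, and 427 with no filter, 667 with the block, 235 with the marker covariate, 351 with offsets, 576 with block and offsets, 560 with DESeq2, 1 with all 36 and 12 to 356 leaving out a library; the higher and lower calls, 81 and 12, were 309 and 118 with no filter and 51 and 75 with the oligodendrocyte covariate. Fear against context gave 0, and 35 with no filter, 784 with the block, 55 with DESeq2 and 0 to 33 leaving out a library. Same-numbered MEC fear libraries did not all deviate together with those of home cage or context. The data therefore give the block behind 3783 and 784 no clear basis.

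For regions, home cage libraries alone gave 185 (MEC and LEC), 639 (CA3 and CA1) and 4794 (entorhinal and hippocampal), and leaving out a replicate 2092 to 3662, 4326 to 5868 and 7971 to 9201. Interactions gave 18, 2, 48 and 115 with DESeq2 for MEC and LEC, CA1 and CA3, entorhinal and hippocampal, and any, 1 with no filter for any, and 1 to 267, 0 to 0, 0 to 3 and 0 to 5 leaving out a replicate; the block changed none of these. Lists called by camera in CA1 (13 after fear, 14 after context, 6 between them), CA3 (10, 7, 2), LEC (7, 6, 9) and MEC (10, 13, 4) were 0 throughout with an estimated correlation, and with fry 0 except 4 in CA3 and 3 in MEC after context and 7 in MEC after fear. The block moved no count of lists by over 1.5 times and ended 3 calls of lists.

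Correlations of responses over the genes called in either region were, after fear, 0.63 (CA1 and MEC), 0.49 (CA3 and MEC) and 0.47 (LEC and MEC), and after context 0.64 (CA1 and CA3), 0.71 (CA1 and MEC), 0.45 (CA3 and LEC), 0.68 (CA3 and MEC) and 0.64 (LEC and MEC). Reversed in direction were C1ql2 in MEC after fear with the oligodendrocyte covariate (0.346), Cbln4 in MEC after context without context 1 (-0.0632, against up to 0.237 without context 2), and, among lists that did not pass, with fry and the block, delayed genes in CA1 between fear and context (adjusted p = 0.978 and 0.97), clock (0.943 and 0.99) and mitochondrial genes (0.959 and 0.959) in CA3 after context, and the cerebellin list in MEC between fear and context (0.973 and 0.817). At these depths 2-fold changes were recovered in 43 to 78 of 100 simulated genes, so a gene that did not pass may still differ.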

Other observations

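Of the tests in this part, those of depth and of the choroid plexus were chosen after the result was seen, and the offsets were added after seeing the data. In the test of the ribosomal decrease against GC content and length, the spread was brought in after the value was seen; without the spread, the value argued against that cause. Cell type lists outside the comparisons above moved as well, and a part of them is given here. In CA1, markers of CA2 (median 1.02) and CA3 pyramidal cells (1.29) were higher after fear than after context (adjusted p = 0.00242 and 0.00695; adjusted p = 0.596 for both with an estimated correlation). Markers of meninges and mural cells lay below home cage in CA1 after fear (-0.796, adjusted p = 0.022; adjusted p = 0.679 with an estimated correlation). Between CA3 and CA1, striatal markers had a median of -0.952 (adjusted p = 0.0411 with an estimated correlation), subiculum markers -2.08, thalamic markers -0.451 and astrocyte markers -0.252 (adjusted p = 0.256, 0.596 and 0.256 with an estimated correlation). Mitochondrially encoded genes lay below home cage after fear in all 4 regions, with medians of -0.796 in CA1, -0.453 in CA3, -0.577 in LEC and -0.42 in MEC (adjusted p = 1.61e-06, 1.2e-05, 1.68e-06 and 0.00787; adjusted p = 0.587, 0.37, 0.487 and 0.826 with an estimated correlation); with GC and length offsets these medians were -0.10, 0.07, -0.19 and 0.11. After context the mitochondrial medians were -0.578 in CA1, 0.0491 in CA3, -0.3 in LEC and -0.452 in MEC. With the offsets they were -0.105, -0.0588, -0.114 and -0.129. Choroid plexus markers had a median of -1.72 in entorhinal against hippocampal regions (adjusted p = 0.00719; adjusted p = 0.373 with an estimated correlation).

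Ribosomal protein genes lay below home cage after fear and after context in all 4 regions, and the mean of the 8 list medians was -0.537. A difference in library depth is argued against as the cause, because the home cage libraries were the deepest on average in 2 of 4 regions. With GC and length offsets the mean was -0.322 (SD 0.11 over the contrasts), so GC content or length bias may account for part of the decrease, and the spread does not decide whether for more than that. The 8 contrasts share home cage libraries within a region and are not independent. A response of the tissue to the behaviour stays open and was not tested. The labels give the same daily handling for home cage, context and fear libraries.

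CA3 fear 2 held transcripts that serve as epithelial markers, among them Krt18 and Krt8, the latter at 113 CPM (at most 1 in the other 8 CA3 libraries). Cdh1 was at 34.6, Msln at 31.2, Sdc1 at 19.3 and Vil1 at 18.3, while Lcn2 was at 0.682. Of 19 epithelial markers not looked at before, 5 lay at least 5 times above the other libraries, among them Krt19 at 82 and Krt7 at 26.7 CPM, but Epcam was at 0.589, Cldn7 at 0.155 and Cldn3 at 0. RNA from epithelial cells may therefore be a candidate source, and the markers that stayed low leave it open. Choroid plexus is argued against, because its list averaged 0.3 log2 CPM in this library against 1.9 in the highest of the others without the filter on low counts, and 0.58 against 2.15 with it. Genes at 5 CPM or more and at least 5 times above the other CA3 libraries numbered 84 in fear 2, 23 in home cage 2 and 0 in the other 7, and without fear 2 the 3 CA3 comparisons gave 0 called genes each.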
